A study of Mus musculus with 2 samples.

How the data were processed

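Gene expression was measured on expression arrays of 45101 probe sets in 2 structures of the mouse hair follicle, the bulge and the hairshaft, with 1 array for each. Per the labels' protocols, skin of 21-day-old C57Bl6 mice was frozen in embedding medium, sectioned, stained with eosin and laser-microdissected. RNA was purified with a kit for very small samples, and 30 ng of total RNA was amplified linearly and labelled with biotin. How the regions were recognised, beyond their names, and the number, sex and body site of the animals are not given in the sources used here. Amplification from little material and dissection from frozen sections can both change the measured values, and with 1 array per structure their spread cannot be estimated.

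The deposited values are log2 probe-set summaries. The authors used GCRMA, per the submitters' processing notes, a method that corrects background from probe sequence, normalizes arrays to each other and summarises the probes of a set; its version and settings are not given in the sources used here. The log2 scale was read from the values, which ran from 2.23 to 15.36. The sorted columns of both arrays differed by at most 0.19 and by 0.045 on average, so the arrays had nearly the same distribution as deposited and no further scaling was applied. The lowest value, 2.23, was shared by 4914 probe sets on the bulge array and 4877 on the hairshaft array. No column of the table was left unused (0 unmatched columns).

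A platform annotation paired 34958 probe sets with 1 gene symbol and 932 with several, and 9211 were unnamed here. Of 64 array control probe sets, 51 were among the unnamed, and 13 carried the symbol Actb, Gapdh, Pcx or Tfrc and stayed in as probe sets of these genes. Symbols were updated through the Entrez identifier for 34754 probe sets against RefSeq gene names of GRCm38.p6, and the other 204 kept the platform's symbol. Coordinates are not given because the array files name no genome build. Each gene took the value of its probe set with the highest mean of both arrays, which gave 18194 genes. An array has no sequencing depth; the number of arrays limits the precision.

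The background floor was set on each array at the 95th percentile of 80 probe sets for olfactory and vomeronasal receptors, which skin was not expected to express. It was 2.68 on both arrays. Genes above it on at least 1 array (13329) entered the comparison. Differences are bulge minus hairshaft on the log2 scale. Where the dimmer array was at or below the floor, the floor took its place and the fold is written as "at least"; this bound rests on the chosen probe set alone. The same bounded differences were used for every count and list median.

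No test was run and no p-value, SD or SE is given, because 1 array per group leaves 0 residual degrees of freedom. Genes were counted at fixed limits of 2-fold and 8-fold. The 33 gene lists were fixed before the data were examined. For each list with at least 5 members above the floor, the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these 2 arrays and not a test between structures. The genes named were the 15 with the largest difference in each direction (probe sets ending in _x_at, predicted genes, ribosomal RNA and controls passed over), up to 4 members with the largest differences from each list with at least 5 members above the floor, and 22 genes chosen in advance, of which 21 were measured; Krt85 was not analysed here. Other members that make up a count of 5 or fewer, and the genes of lists with under 5 members above the floor, are also named, chosen after their values were seen.

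The counting and the random lists were tested on simulated data for this comparison, with 18194 genes, noise of 0.3 (SD, log2) on each array and 200 changed genes drawn from those with a mean over 6 (log2). Of the genes changed by 4-fold and of those changed by 16-fold, 100% were counted at the 2-fold limit in the right direction, as were 1.69% of unchanged genes in either direction. A 20-gene list shifted by 1 log2 unit lay at percentile 100. Another 100 lists were drawn at random from all genes above the floor, changed genes included, and each was set against 500 random lists. Of these, 6 fell outside the middle 95%. Such a share follows from the random draw, so it checks the procedure only and not lists of genes expressed together. The simulated noise was chosen, not measured.

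There were 9 alternatives for each count, list and named gene. They were the 99th percentile of the receptor probe sets as floor, the median of all probe sets as floor, no floor, the mean of a gene's probe sets, only plain probe sets (without _a_at, _s_at and _x_at), an offset of 16 added on the linear scale, removal of a loess trend (span 0.3), removal of the median difference, and quantile normalization. Leaving out a replicate was not possible. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 were used.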

Results

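Expression was compared between the bulge, the part of the follicle's outer root sheath that houses hair follicle stem cells, and the hairshaft, both cut by laser from skin of 21-day-old C57Bl6 mice. There was 1 array for each structure. All values are log2 GCRMA values of these 2 arrays, without replicates, so no difference could be set against a replicate spread. Folds and counts describe these 2 arrays only, and their number limits the precision.

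The bulge array carried far more genes with large differences than the hairshaft array. Of 13329 genes above the floor, 1526 were at least 2-fold higher in the bulge and 655 at least 2-fold higher in the hairshaft. At 8-fold the counts were 402 and 25, so that 94.1% of the genes this far apart were higher in the bulge. The 8-fold count in the bulge became 233 with the offset of 16, and that in the hairshaft 14 with the 99th percentile floor, 15 with the mean of probe sets and 10 with the offset. The other 11148 genes (83.6%) were under 2-fold apart, and the correlation across genes above the floor was 0.90 (Pearson; genes are not independent replicates). The only repeat measurement was between probe sets of the same gene. Among genes with 2 or more probe sets above the floor, all probe sets had the same direction for 3126 of 6256 genes, for 472 of 663 genes (71.2%) at least 2-fold higher in the bulge and for 219 of 299 (73.2%) higher in the hairshaft. Of 156 named genes above the floor, 93 had a difference that moved by over 1.5-fold with at least 1 of 9 alternatives, nearly always to a smaller one (235 of 236 values), so folds of genes dim on 1 array depend on the floor and the probe set.

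**Figure D1:**
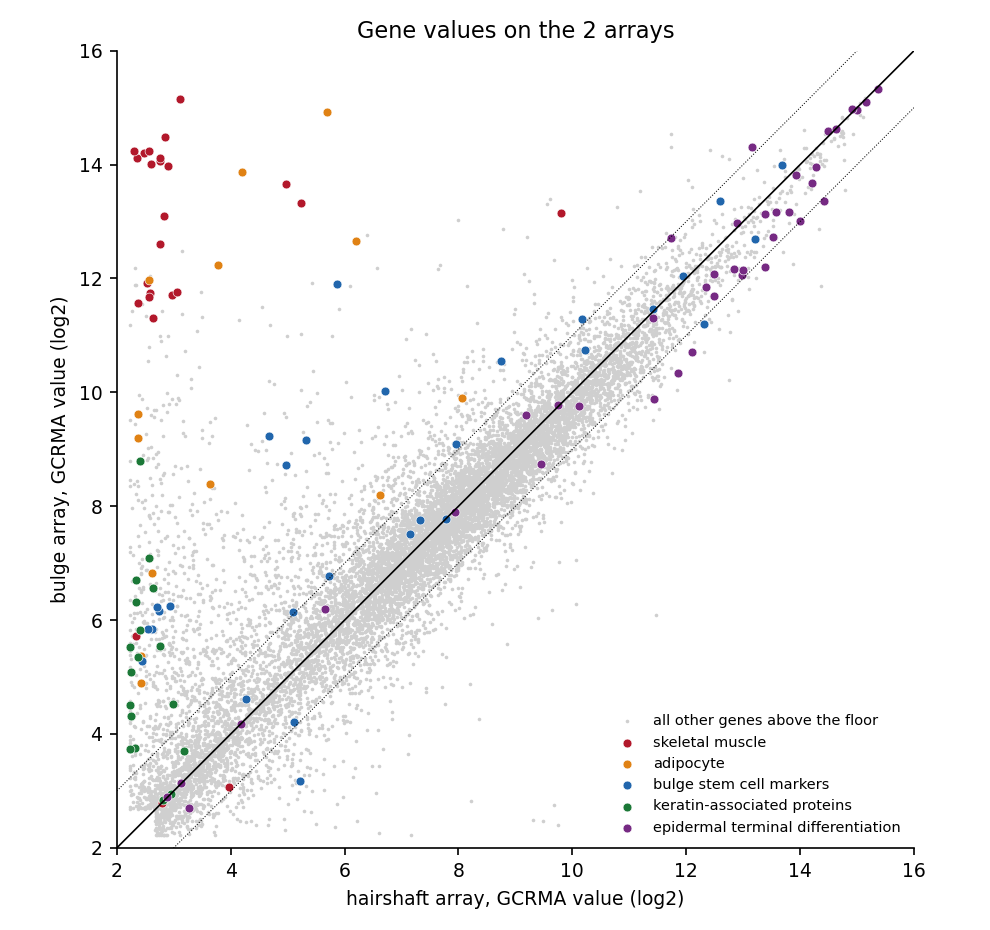
Log2 GCRMA value of each gene above the floor on the hairshaft array (x axis) and on the bulge array (y axis), with 5 gene lists in colour; the solid line marks equal values and the dotted lines a 2-fold difference. Most genes lie between the dotted lines, while 23 of 25 skeletal muscle genes lie at least 8-fold above the diagonal on the bulge side.

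Stem cell markers of the bulge were mostly higher in the bulge array. Lhx2, a transcription factor of follicle stem cells, had 9.23 in the bulge and 4.67 in the hairshaft, a 23.6-fold difference. Sox9, which specifies the outer root sheath, was 13.5-fold higher, Foxc1 14.3-fold and Lgr5, a receptor that marks cycling follicle stem cells, 10.6-fold. With the mean of probe sets the log2 difference of Sox9 was 2.11 in place of 3.76 and that of Lgr5 1.52 in place of 3.41, and with the 99th percentile floor Lgr5 had 1.94. The surface marker Cd34 was 3.46-fold higher and Nfatc1, a regulator of stem cell quiescence, 2.19-fold (a log2 difference of 1.13, or 0.85 with the mean of its probe sets). Krt15, a classical bulge keratin, was 13.99 in the bulge and 13.68 in the hairshaft, only 1.24-fold apart. These values are near the top of the scale, where signals can be compressed, so they do not show equal expression. In the list of bulge stem cell markers, 16 of 29 members were at least 2-fold higher in the bulge, 2 in the hairshaft (Dio2 and Itga6) and 11 were under 2-fold apart. Its median difference of 1.06 lay above all 10000 matched random lists (percentile 100). The largest member difference was in Ccn2, a matrix-associated growth factor, at 66.0-fold; 15 of the list's measured genes are also in another list, and the muscle, fat and vessel lists were higher in the same array.

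Keratinocyte keratins read nearly equal, and near the top of the scale, on both arrays. Krt5, a keratin of basal cells and of the outer root sheath, was 13.96 on both arrays, and its partner Krt14 was 14.38 in the bulge and 14.40 in the hairshaft. In the list for basal keratinocyte adhesion, 14 of 16 members were under 2-fold apart, with a median of -0.03 (percentile 72.0) that became 0.12 with the loess trend removed. Lama5, a laminin chain, was 2.72-fold higher in the bulge and Itga6, the alpha-6 integrin, 2.15-fold higher in the hairshaft, and with the mean of probe sets both were under 2-fold apart (log2 differences of 0.61 and -0.68). The outer root sheath and companion layer list had 8 of 12 members under 2-fold apart and a median of 0.21 (percentile 94.3). The other members were Krt75, the companion layer keratin, at least 70.5-fold higher in the bulge (log2 6.14, or 4.60 with the 99th percentile floor), Fzd7 and Krt79, also higher in the bulge, and Krt6b, 2.29-fold higher in the hairshaft. Of 11 genes of the upper follicle, 8 were at least 2-fold higher in the bulge, none in the hairshaft and 3 under 2-fold apart (Lgr6, Krt17 and Krt80). The list median was 1.44 (percentile 100). Among the 8 were Gata6 at 7.92-fold (log2 2.99, or 1.54 with the mean of probe sets), the defensin Defb6 at 5.93-fold, Krt79 at 5.12-fold and Klk10 at 3.52-fold.

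Hair keratins and other products of the differentiating hair were higher in the bulge array, not in the hairshaft array. Krt33a was at least 21.1-fold, Krt31 at least 10.8-fold and Krt86 at least 6.75-fold higher in the bulge, and Krt34 was 4.21-fold higher. Their bulge values were modest, at 7.07 for Krt33a, 6.11 for Krt31, 5.43 for Krt86 and 5.65 for Krt34, over a floor of 2.68. Of 10 hair shaft keratins above the floor, 6 were at least 2-fold higher in the bulge and 4 (Krt32, Krt35, Krt36 and Krt83) were under 2-fold apart. Keratin-associated proteins, which embed the keratin filaments of the hair, were at least 2-fold higher in the bulge for 15 of 18 members above the floor, all but Krtap7-1, Krtap17-1 and Krtap21-1. The largest differences were in Krtap8-1 (at least 69.8-fold), Krtap22-2 (at least 21.3-fold) and Krtap4-6 (at least 16.3-fold). With the 99th percentile floor the log2 differences were 2.86 for Krt33a, 1.90 for Krt31, 1.22 for Krt86, 1.43 for Krt34 and 4.59 for Krtap8-1. The list medians were 1.87 for the hair shaft keratins and 2.54 for the keratin-associated proteins, both at percentile 100. Members of the keratin-associated protein family are similar in sequence, so their probe sets can share signal, and 20 of the 38 measured were not above the floor on either array. Without a floor, the median over all 38 was 0.0382, and that of the 12 hair shaft keratins 1.14.

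The inner root sheath, the layer that moulds the growing hair, showed the same direction. Krt25 was 57.6-fold higher in the bulge, trichohyalin (Tchh) 56.8-fold, Krt27 25.0-fold and Krt71 18.3-fold. Of 16 members of this list, 7 were at least 2-fold higher in the bulge, none in the hairshaft and 9 were under 2-fold apart; the median was 0.74 (percentile 99.9). Gata3, which specifies the inner root sheath and is also expressed in epidermis, was 1.42-fold higher in the hairshaft. In the list of hair differentiation regulators and cortex genes, 14 of 19 were under 2-fold apart. Its median of 0.01 lay inside the range of random lists (percentile 85.3). Hoxc13, a regulator of hair keratin genes, was 2.85-fold higher in the bulge (a log2 difference of 1.51, or 0.51 with the 99th percentile floor), as were Lap3, a peptidase, at 3.73-fold, Selenbp1 at 3.18-fold and S100a3 at least 2.69-fold (under 2-fold with the median of all probe sets as floor, log2 0.63, and the offset, 0.57). Nkd2, a Wnt inhibitor, was the 1 member at least 2-fold higher in the hairshaft. Foxn1, the nude gene, was 1.60-fold higher in the hairshaft, and Lef1 was at or below the floor on both arrays (2.62 and 2.29).

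**Figure D2:**
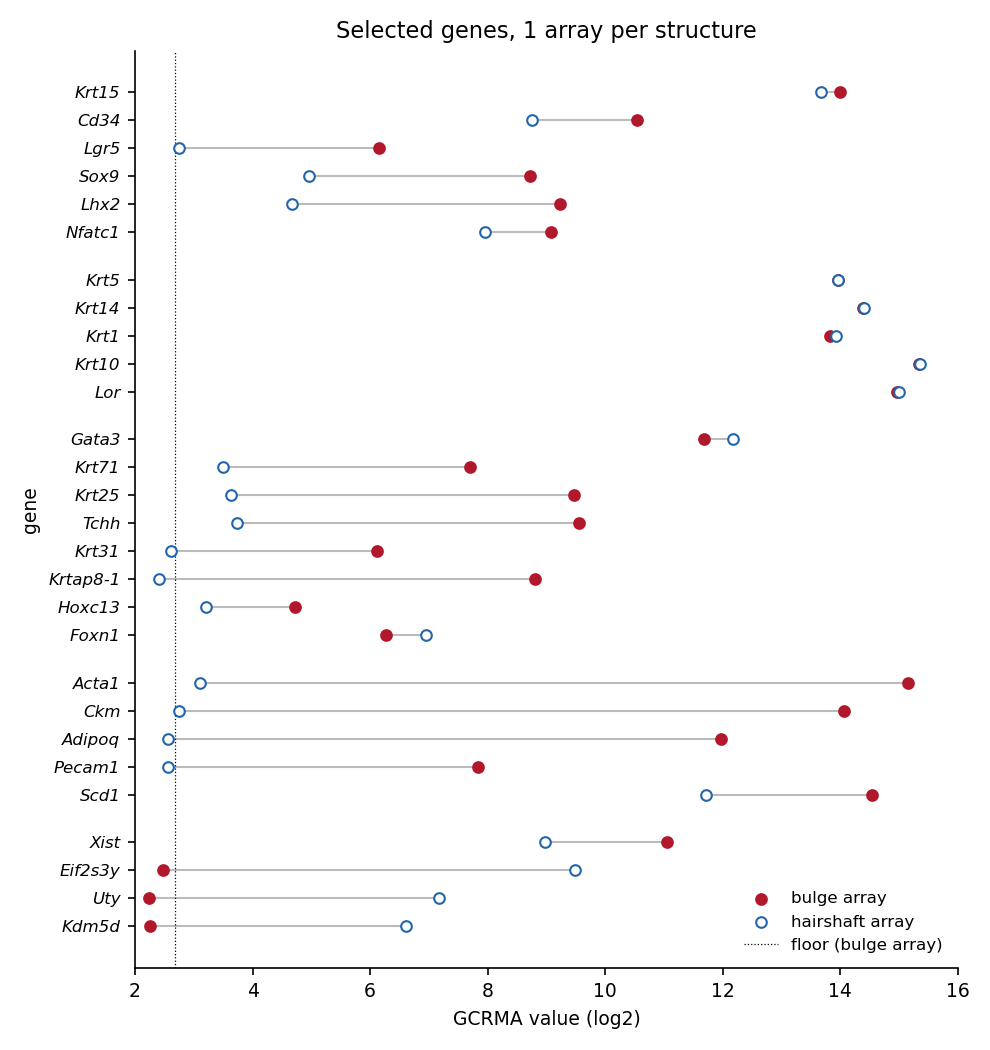
Log2 GCRMA value (x axis) of selected genes (y axis) on the bulge array (filled red) and the hairshaft array (open blue), joined by a line, with the background floor of the bulge array dotted. Krt5, Krt14, Krt1, Krt10 and Lor nearly coincide, hair and inner root sheath genes other than Gata3 and Foxn1 are higher in the bulge, and the Y-linked Eif2s3y, Uty and Kdm5d are above the floor only in the hairshaft.

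Genes of terminal epidermal differentiation were above the floor in the list's 39 measured members and as a group slightly higher in the hairshaft array. Krt10, a keratin of suprabasal epidermis, was 15.33 in the bulge and 15.36 in the hairshaft, Krt1 was 13.82 and 13.93, and loricrin (Lor), a main cornified envelope protein, 14.97 and 15.01; with the loess trend removed these 3 were slightly higher in the bulge, as were Krt5 and Krt14. The Krt10 value was the highest on each array, and signals this near the top of the scale can be compressed, so near-equal values there do not show equal expression. Of 39 genes in this list, 5 were at least 2-fold higher in the hairshaft, 1 (Cst6) in the bulge and 33 were under 2-fold apart, with a median of -0.33 (percentile 0.46). The 5 were the protease Casp14 at 2.93-fold (a log2 difference of -1.55, or -0.97 with the mean of probe sets), Lce1c, Klk8 at 2.86-fold, involucrin (Ivl) at 2.63-fold and corneodesmosin (Cdsn) at 2.26-fold. Desmosome genes had a median of -0.36, inside the range of random lists (percentile 4.59), and 13 of 14 were under 2-fold apart, all but Pkp2, which was 4.31-fold higher in the bulge with its brightest probe set and under 2-fold with the mean of its probe sets (log2 difference 0.54). The small proline-rich and late cornified envelope families had a median of 0.00 (percentile 65.2), with 18 of 23 under 2-fold apart, Sprr2d at 9.30-fold, Sprr2f, Sprr2i and Lce3f higher in the bulge and Lce1c higher in the hairshaft. Sprr2i was under 2-fold with the 99th percentile floor (log2 0.38) and the offset (0.61), and Lce3f with the median of all probe sets as floor (0.42) and the offset (0.45).

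The largest differences of all were in genes of skeletal muscle. Acta1, the alpha-actin of skeletal muscle, was 15.15 in the bulge and 3.11 in the hairshaft. The troponins Tnni2, Tnnc2 and Tnnt3 had 14.48, 14.23 and 14.11 in the bulge, and creatine kinase Ckm and the myosin heavy chain Myh4 had 14.07 and 13.98; all 5 were below 3 in the hairshaft. Of 25 skeletal muscle genes, 23 were at least 8-fold higher in the bulge, with a list median of 9.25 (percentile 100), and the other 2, Myh3 and Tnnt1, were under 2-fold apart. Of the 15 genes with the largest difference in this direction, 13 were muscle genes (Acta1, Tnni2, Myl1, Tnnc2, Atp2a1, Tnnt3, Ttn, Ckm, Myh4, Pvalb, Tcap, Mybpc2 and Apobec2) and the others were the fat cell genes Fabp4 and Adipoq.

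Fat, vessel and smooth muscle genes were higher in the bulge array as well. All 13 adipocyte genes above the floor were at least 2-fold higher there, with a median of 6.46. The fatty acid carrier Fabp4 was 821-fold (log2 9.68, or 4.90 with plain probe sets), Car3 600-fold and the fatty acid transporter Cd36 354-fold higher, and adiponectin (Adipoq) at least 625-fold. With the mean of probe sets the log2 difference of Car3 was 8.16 in place of 9.23 and that of Cd36 7.31 in place of 8.47. Adipoq had 7.75 in place of 9.29 with the 99th percentile floor. Of 21 endothelial genes, 17 were at least 2-fold higher in the bulge (median 2.72), all but Eng, Egfl7, Erg and Prox1, among them Aplnr at 52.7-fold and Pecam1 at least 35.6-fold (log2 differences of 1.06 with plain probe sets and 3.62 with the 99th percentile floor). Smooth muscle and arrector pili genes were at least 2-fold higher for 11 of 16 (median 1.504), all but Myocd, Smtn, Kcnmb1, Notch3 and Pcp4, with desmin (Des), which skeletal muscle also makes, at 89.9-fold (log2 6.49, or 3.25 with the mean of probe sets), Rgs5 at 30.6-fold, Actg2 at 6.30-fold and Tagln at 4.11-fold. These 3 medians lay at percentile 100. The nerve and Schwann cell list had a median of 0.22 (percentile 94.7) with 10 of 13 under 2-fold apart; Cdh19 was 7.65-fold (log2 2.94, or 1.46 with the 99th percentile floor), Pmp22 2.15-fold and Sox10 2.09-fold higher in the bulge, Sox10 being under 2-fold with the mean of probe sets (log2 0.35), the offset of 16 (0.74) and quantile normalization (0.90). In the erythroid list 4 genes were above the floor, each under 2-fold apart (Hbb-b2, Slc4a1, Epb42 and Car2).

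Lipid genes of the sebaceous gland were higher in the bulge array. Of 21 members, 14 were at least 2-fold higher in the bulge and none in the hairshaft, with a median of 2.65 (percentile 100). Elovl3, a fatty acid elongase, was 186-fold higher, Cidea 128-fold, the wax-forming reductase Far2 90.9-fold, and Pparg, a regulator of lipid storage shared with fat cells, at least 39.0-fold. Scd1, a desaturase of sebocytes and fat cells, was 14.54 in the bulge and 11.72 in the hairshaft (7.06-fold). Adipocyte genes were higher in the same array, and the lists do not separate these sources. With the 99th percentile floor the log2 differences were 6.52 for Elovl3, 6.24 for Cidea and 3.75 for Pparg. Melanocyte genes had a median of 1.51 (percentile 99.9), with 6 of 10 at least 2-fold higher in the bulge, Gpnmb higher in the hairshaft, and Kit, Slc45a2 and Rab38 under 2-fold apart; without a floor the median over all 16 measured was 0.00. The pigment enzyme Dct was higher in the bulge by at least 4.32 (log2), Ednrb was at least 13.5-fold and Pmel 5.81-fold higher in the bulge. With the 99th percentile floor the log2 differences were 2.78 for Dct, 2.22 for Ednrb and 1.28 for Pmel.

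Genes of the dermis were divided. In the fibroblast and matrix list, 10 of 30 members were at least 2-fold higher in the hairshaft and 6 in the bulge, and the median of -0.52 lay below all random lists (percentile 0.00). The main collagen chain Col1a1 was 11.87 in the bulge and 14.36 in the hairshaft (5.61-fold), and elastin (Eln) was 3.71-fold higher in the hairshaft. Ccl11, a chemokine of fibroblasts, was at least 14.1-fold (log2 3.82, or 2.28 with the 99th percentile floor) and Mfap5 4.11-fold higher in the bulge. Dermal papilla genes had 12 of 18 members under 2-fold apart and a median of 0.17 (percentile 88.9), with Igfbp4 (11.11 in the bulge, 7.16 in the hairshaft), Sox18, also in the endothelial list, at 6.45-fold (log2 2.69, or 1.39 with that floor), Fgf7 at 6.28-fold (2.65, or 1.42 with the mean of probe sets), Spon1 (under 2-fold with the mean of probe sets, log2 0.47) and Notum higher in the bulge and Vcan higher in the hairshaft.

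Immune genes were slightly higher in the hairshaft array. Of 29 members, 27 were under 2-fold apart, with a median of -0.35 (percentile 0.43). The exceptions were the class II gene H2-Eb1, 6.09 in the bulge and 11.47 in the hairshaft (41.7-fold), and the T cell gene Cd3e (2.78-fold). The macrophage receptor Csf1r and the leukocyte actin regulator Coro1a were 1.97-fold and 1.81-fold higher in the hairshaft. Mast cell genes had a median of -0.87 (percentile 0.01), with 4 of 8 at least 2-fold higher in the hairshaft, led by carboxypeptidase Cpa3 at 4.75-fold, Ms4a2 at 4.01-fold (a log2 difference of -1.07 with the 99th percentile floor) and the chymase Cma1 at 2.74-fold, with Tpsb2 at 2.15-fold (a log2 difference of -1.11, but -0.23 to -0.92 with 4 of the 9 alternatives); Mcpt4, Fcer1a, Kit and Gata2 were under 2-fold apart.

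**Figure D3:**
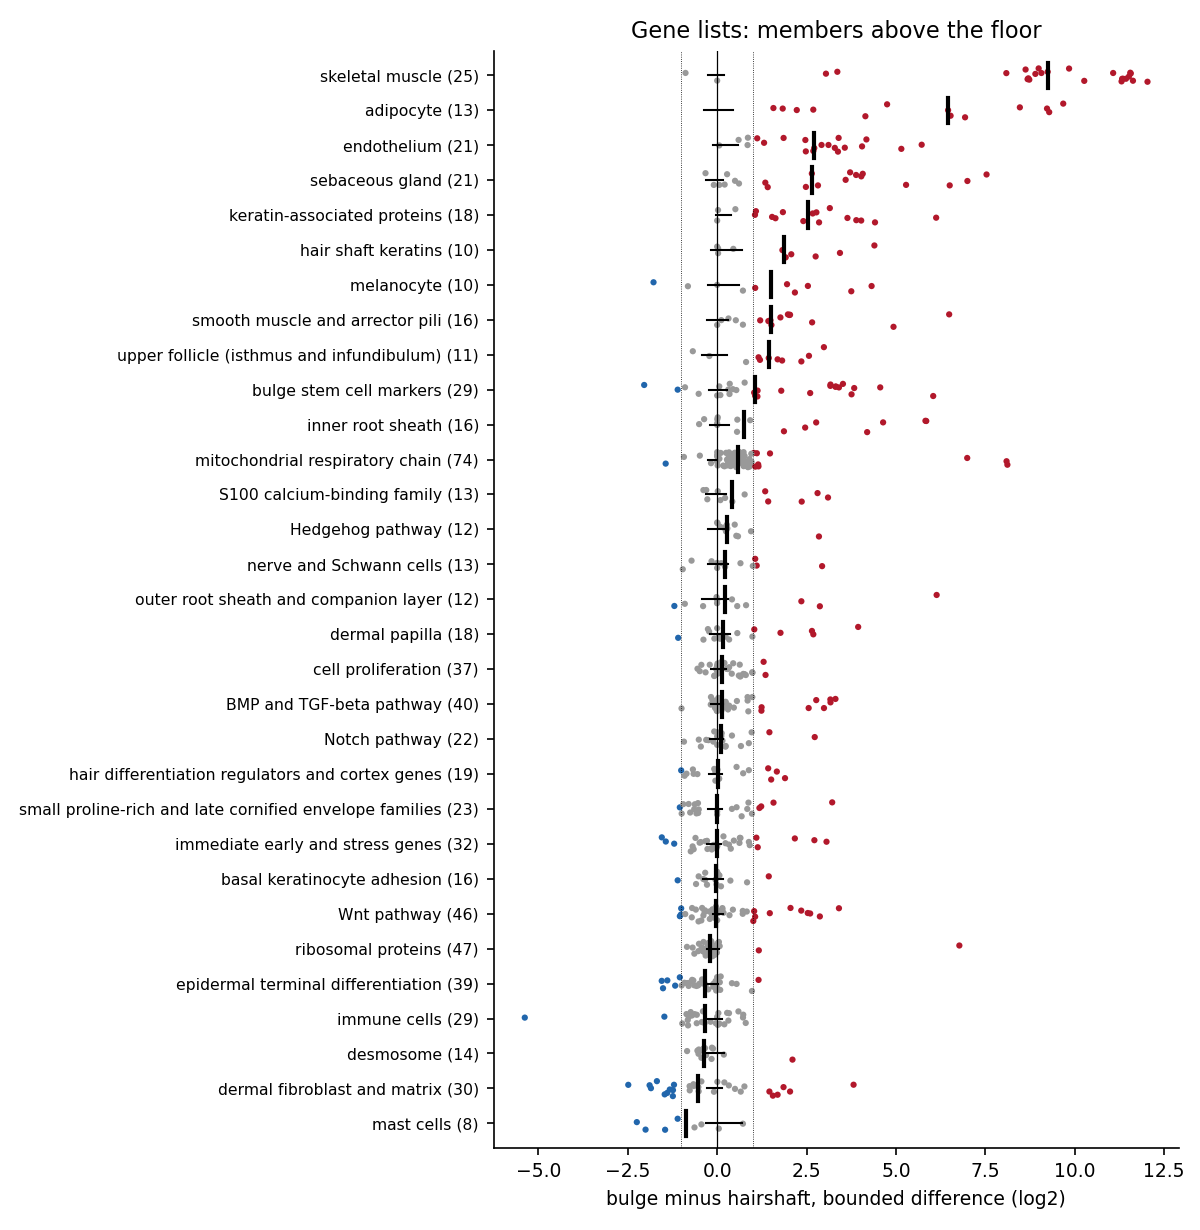
Bounded difference, bulge minus hairshaft (x axis, log2), of each member above the floor in the 31 gene lists with at least 5 such members (y axis, number in parentheses); red and blue points are at least 2-fold higher in the bulge and in the hairshaft, thick bars are list medians and thin lines the middle 95% of matched random lists. The medians run from -0.87 for mast cells to 9.25 for skeletal muscle.

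Proliferation genes were close on both arrays. Mki67, a marker of cycling cells, was 9.90 in the bulge and 9.88 in the hairshaft. Of 37 members, 35 were under 2-fold apart (median 0.14, percentile 89.9), and the exceptions, Aurkb and Kif20a, were 2.55-fold and 2.46-fold higher in the bulge, and under 2-fold with the mean of probe sets (Aurkb, log2 0.84) or the offset of 16 (Kif20a, log2 0.80). Most genes of the 4 signalling pathways were also under 2-fold apart, namely 33 of 46 for Wnt (median -0.04, percentile 11.8), 32 of 40 for BMP and TGF-beta (0.13, percentile 96.4), 11 of 12 for Hedgehog (0.28, percentile 98.4) and 20 of 22 for Notch (0.10, percentile 95.1). The Wnt list's mean of 0.31 had the opposite sign to its median. The named members furthest apart were higher in the bulge. Follistatin (Fst), which binds activins and BMPs, was 9.91-fold, the latent TGF-beta binding protein Ltbp2 at least 8.98-fold, the ligand Tgfb3 at least 7.94-fold, the Wnt receptors Fzd7 and Fzd3 7.32-fold and 5.79-fold, the Wnt inhibitor Wif1 at least 6.07-fold, the transcription factor Gli2 7.20-fold and Dtx4, a ubiquitin ligase, 6.63-fold higher, and the ligand Bmp6 was higher by at least 3.17 (log2). The ligands Wnt3 and Wnt7b and the inhibitor Nkd2 were at least 2-fold higher in the hairshaft. For Fzd3, the mean over its 6 probe sets gave a log2 difference of 0.41 in place of 2.53, and that of Fzd7 became 1.44 in place of 2.87; with the 99th percentile floor Ltbp2 had 1.63, Tgfb3 1.45, Wif1 1.07 and Bmp6 1.64.

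Stress and housekeeping genes showed small list differences. Immediate early and stress genes had a median of -0.01 (percentile 78.3; 0.13 with the loess trend removed) and a mean of 0.20, with 24 of 32 under 2-fold apart; Klf2 was 8.33-fold and Nr4a1 6.59-fold higher in the bulge, with Fosb, Egr1 and Ccn1 also at least 2-fold higher there, and the chaperone Hsph1 was 2.93-fold higher in the hairshaft, as were Hspa1a and Dnajb1 at over 2-fold. The probe sets of Ccn1 disagreed, at 2.17, 2.69, -2.14 and -2.95 (log2 differences). Ribosomal protein genes had a median of -0.19 (percentile 15.9), and the furthest apart was Rpl3l, a muscle form, at 110-fold higher in the bulge (log2 6.78, or 5.44 with the 99th percentile floor); Rpl39l was 2.24-fold higher there and the other 45 of 47 were under 2-fold apart. Genes of the mitochondrial respiratory chain had a median of 0.58 (percentile 100) with 64 of 74 under 2-fold apart, 9 higher in the bulge and 1, Ndufa4l2, in the hairshaft. The 3 members at least 8-fold higher in the bulge, Cox6a2 (278-fold), Cox8b (274-fold) and Cox7a1 (128-fold), are isoforms of muscle or brown fat. With the 99th percentile floor their log2 differences were 6.69, 6.79 and 5.47, the first 2 in place of 8.12 and 8.10. In the S100 family, S100a1, which muscle makes, was 8.58-fold and S100a9 5.15-fold higher in the bulge, and S100a8 was 9.40 in the bulge and 6.59 in the hairshaft (list median 0.42, percentile 99.7). S100a3 and S100pbp, a binding protein outside the family that the list's name pattern took in, were the other 2 of 13 at least 2-fold higher in the bulge.

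Few genes were much higher in the hairshaft array. The 15 with the largest difference in this direction were Rpgrip1 (at least 134-fold), the peptide transporter Slc15a2 (122-fold), Eif2s3y (at least 111-fold), Ang (at least 98.6-fold), H2-Eb1 (41.7-fold), Uty (at least 22.5-fold), Apol7a (17.1-fold), Kdm5d (at least 15.2-fold), Gadl1 (13.8-fold), Zfp458 (12.1-fold), perforin (Prf1, at least 11.7-fold), Mycn (11.1-fold), Adh6a (11.0-fold), Il6ra (10.3-fold) and Abca12, a lipid transporter of the skin barrier (a log2 difference of -3.33). With the mean of probe sets the log2 difference of Rpgrip1 was -1.68, of Slc15a2 -2.07 (in place of -6.93), of Eif2s3y -3.18, of Kdm5d -1.35, of Zfp458 -1.72, of Prf1 -1.55 and of Mycn -1.16, and with plain probe sets that of Ang was -1.21. With the 99th percentile floor Slc15a2 had -5.47. These genes had 19 other probe sets, of which 7 were at least 2-fold higher in the hairshaft; for the 15 genes of the bulge, 10 of 13 other probe sets were at least 2-fold higher in the bulge. The 3 other Rpgrip1 probe sets and the other Slc15a2 probe sets were near the floor on both arrays and under 2-fold apart, and those of Ang were 2.99 and 5.15 in the bulge and 7.81 and 6.36 in the hairshaft.

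The 3 Y-linked genes measured were, by their brightest probe sets, above the floor only on the hairshaft array. Eif2s3y was 2.48 in the bulge and 9.48 in the hairshaft, Uty 2.23 and 7.17, and Kdm5d 2.26 and 6.61. The 4 Uty probe sets differed by -3.20 to -4.94 (log2), and 1 of them was just above the floor in the bulge at 2.70, whereas other probe sets of Eif2s3y and Kdm5d were under 2-fold apart. Xist, the RNA of the inactive X chromosome of females, was well above the floor on both arrays, at 11.06 in the bulge and 8.98 in the hairshaft (4.22-fold) by its brightest probe set, while its other probe sets differed by 0.68 and -0.28 (log2).

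The array controls gave the following values. The poly-A spikes Dap, Lys, Phe and Thr, which enter before labelling, differed by 0.22 to 0.56 over 24 probe sets (log2, higher on the bulge array). The TrpnX control probe sets, not counted among them, differed by 0.21 to 0.53 in the same direction. Hybridisation spikes differed by -0.55 to -0.06 (higher on the hairshaft array) over 18 probe sets. The difference between 3' and 5' probe sets, a measure of RNA integrity, was 0.61 in the bulge and 1.62 in the hairshaft for Actb. For Gapdh it was -0.14 and 0.16. Between 3' and middle probe sets the arrays were close for Actb, at 1.86 in the bulge and 1.80 in the hairshaft, and Gapdh had 0.15 and 0.43. The 5' probe sets of Tfrc (2.86 on both arrays) and Pcx (3.45 in the bulge and 3.35 in the hairshaft) were near background, so these genes do not measure integrity here. The 3 Gapdh controls averaged 14.14 in the bulge and 12.43 in the hairshaft, and the 3 controls for 18S ribosomal RNA 3.05 and 4.36.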

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

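The probe sets without a single gene symbol, array controls aside, took no part in the comparison, and large differences appeared among them too. Of 10092 such probe sets, 4497 were above the floor on at least 1 array. At least 8-fold differences were found in 59 probe sets higher in the bulge and in 25 higher in the hairshaft, together 1.87% of those above the floor against 3.20% of named genes. At 2-fold, 346 were higher in the bulge and 482 in the hairshaft, whereas named genes had 1526 and 655. Each unnamed probe set counted singly, whereas a named gene was represented by its probe set with the highest mean. These shares and counts are therefore not like for like.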

How the results depend on the processing

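With 1 array per structure no replicate could be left out, and signal near background limits the differences of dim genes. The 2-fold counts stayed within 1.5 times of 1526 and 655 under all 9 alternatives. Removal of the median difference gave the main counts again, because the median difference was 0.00, so it could move no result. This alternative therefore adds nothing to the stability of the counts, lists and named genes. The 8-fold count in the hairshaft (25) became 14 with the 99th percentile floor, 15 with the mean of probe sets and 10 with the offset, and the 8-fold count in the bulge (402) became 233 with the offset. No list median outside the random range turned its direction; 259 of 278 list values moved by under 1.5-fold; mast cells gave no value with plain probe sets, as under 5 members were left. Those that moved further were, with the 99th percentile floor, the medians of hair shaft keratins (1.22), keratin-associated proteins (1.33), endothelium (1.90) and adipocytes (4.99). With the median of all probe sets as floor they were inner root sheath (1.66) and adipocytes (5.73). Without a floor they were hair shaft keratins (1.14), keratin-associated proteins (0.0382) and melanocytes (0.00), since genes at background on both arrays then enter. With the mean of probe sets they were sebaceous gland (2.04) and melanocytes (0.86), and with plain probe sets sebaceous gland (1.95) and adipocytes (5.68). With the offset they were hair shaft keratins (0.98), keratin-associated proteins (1.25), melanocytes (0.87), endothelium (1.63), skeletal muscle (8.09) and adipocytes (4.76), because an offset shrinks differences of dim genes. Of 1376 values of named genes, 236 (in 93 genes) moved by over 1.5-fold, 235 to a smaller difference and 1 (Selenbp1, mean of probe sets) to a larger one. Of 130 named genes at least 2-fold apart, 111 stayed so in every alternative that gave a value. Of these 130, Ccn1 was the only one to reverse, from 2.17 to -0.0576 with the mean of probe sets and -2.95 with plain probe sets; its probe sets disagree, and the cause was not tested.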

Other observations

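The tests for cross-hybridising probe sets, for dropout within the range of the Y-linked genes and for H2-Ea were set before their results were seen, and the other tests and gene groups here were chosen only after. Genes of fast and slow muscle fibres were set side by side after fast-fibre genes such as Tnni2, Tnnt3 and Myh4 had been seen among the largest differences. All 11 fast-fibre genes were at least 8-fold higher in the bulge (median 11.36), which that choice largely fixed; Myh1 had 14.20 and Mylpf 13.66 in the bulge. Of 11 genes of slow fibres and heart, 5 were above the floor and Myoz2 was the one at least 8-fold higher in the bulge, while Tnnt2 was 3.25-fold higher in the hairshaft; the slow myosin Myh7 was 2.33 on both arrays, Myl2 2.33 and Tnnt1 2.79. Among myogenic factors, Myf6 (7.20 in the bulge, 2.23 in the hairshaft) and Mef2c (9.20 and 3.49) were higher in the bulge, while Pax7, Myf5, Myod1 and Myog were at or below the floor on both. Of 8 brown and beige fat genes above the floor, 5 were at least 2-fold and 4 at least 8-fold higher in the bulge (median 4.26). These 4, whose values had been seen before the list was made, were Cidea and Elovl3, also in the sebaceous gland list, and Cox8b and Cox7a1, also in the respiratory chain list. Ppargc1a was 2.87-fold higher in the bulge, Dio2 and Zic1 were 4.12-fold and 2.41-fold higher in the hairshaft, and Ucp1, the uncoupling protein of brown fat, was below the floor on both arrays (2.27 and 2.30).

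Hox genes, which carry body position in skin and muscle, were mostly close on both arrays. Of 24 above the floor, 19 were under 2-fold apart, 5 were at least 2-fold higher in the bulge and none in the hairshaft (median 0.10, percentile 91.6). The furthest apart were Hoxd9 (6.43 in the bulge, 3.12 in the hairshaft; 9.90-fold) and Hoxd8 (8.35 and 5.34; 8.04-fold). Hoxc8 (8.11 and 6.91), Hoxa9 (8.06 and 6.98) and Hoxc13 were the others.

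Skeletal muscle and fat transcripts made up the largest differences in the bulge array. For array-wide scaling that differs with signal level, removing a loess trend left the muscle list median at 9.27 (log2). The sorted columns differed by at most 0.19 as deposited, so little array-wide trend was left to remove and that outcome was nearly fixed. The value speaks only to scaling left in the deposited values. Cross-hybridising probe sets are argued against by a median of 8.82 with plain probe sets. Unequal amplification of transcripts stays open. The poly-A spikes, which differed by at most 0.56, averaged 14.43 and 14.07, near the top of the scale, and the hybridisation spikes are not amplified. The TrpnX control probe sets lay lower (10.34 to 11.72) and differed by 0.21 to 0.53, but this control alone does not stand for the muscle and fat transcripts. RNA of muscle and fat tissue in the dissected bulge material is a candidate explanation that stays open. The 23 of 25 muscle genes at least 8-fold higher (Acta1 at 15.15, Ckm at 14.07) are the pattern itself and no independent support for it. A difference between the structures themselves was not tested.

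Some genes were near background in the bulge array and well above it in the hairshaft array. General dropout of transcripts in the bulge array is argued against, because of 5223 genes within the range of the Y-linked genes on the hairshaft array (6.61 to 9.48) only 0.0766%, namely Ang and the 3 Y-linked genes, were at or below the floor in the bulge by their brightest probe sets. That range leaves out Rpgrip1, Prf1 and Spata5l1; over all 8698 genes at least 8-fold above the floor on the hairshaft array, these 3 and the former 4 made up 0.0805%. Animals of different sex in the 2 dissections (Y-linked genes) is a candidate explanation that stays open; the 3 of 3 such genes above the floor on 1 array only are among the genes that showed the pattern, and Xist was above the floor on both arrays. What sets Rpgrip1, Slc15a2, Ang, Prf1 and Spata5l1 apart stays open, strain variants and variants under single probe sets included.

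H2-Eb1, at 6.09 in the bulge and 11.47 in the hairshaft, was above background on both arrays and is not part of that pattern. H2-Ea, held to be absent from this strain, read 6.83 in the bulge and 7.44 in the hairshaft (a difference of -0.61), so its probe set or that premise fails and it gave no test of the H2 haplotype.

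Hair keratin genes were not higher in the hairshaft array. Whether the 2 arrays carry each other's label stays open. The median of the bulge stem cell list lay at percentile 100 in the direction of the bulge label, but 15 of its genes are in other lists. The hair shaft keratin, skeletal muscle, adipocyte, endothelium and sebaceous gland lists also lay at percentile 100 on that side. The stem cell list therefore does not decide how the arrays were labelled. The candidate explanation "no hair-forming matrix in the hairshaft dissection" stays open. Of 12 measured hair shaft keratins, 1 (Krt32, with exactly equal values on both arrays) lay over 2 log2 units above the floor there and 7 on the bulge array, which restates the pattern and does not bear on its cause. A difference between the structures themselves stays open and was not tested.

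Exactly equal values on both arrays were common. They made up 38.3% of all probe sets and 11.5% of those above the floor, 27.5% at a mean log2 value of 3 to 4 and 0.403% at 8 or more. A difference of exactly 0 in a dim gene thus says little about that gene.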
